A study of Mus musculus with 8 samples.

How the data were processed

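Poly(A) RNA of mouse bone marrow-derived macrophages was sequenced in 8 libraries, with 2 libraries in each of 4 groups. Wild-type and Nrf2 knockout cells, the latter from mice of a commercial breeder, were differentiated for 7 days and were left untreated or given 250 µM dimethyl itaconate (DI) for 12 h, per the labels. The labels' extract protocol describes an oligo-dT primer carrying a library barcode and a run of 15 T, pooling of libraries after first-strand synthesis by the level of Actb, ligation of an adaptor and 12 PCR cycles, which yields strand-specific reads near transcript 3′ ends. No molecular identifier is described, so reads of the same molecule cannot be told from separate molecules. A primer with a run of T can also anneal to runs of A inside a transcript. The deposited values are raw counts per Ensembl gene and library, with no normalization, for 22165 genes. The submitters' processing notes name mm10, STAR, HTSeq and DESeq2 without versions or settings, and the annotation release used for counting is not given in the sources used here.

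The deposited counts were matched to GENCODE release M21 (GRCm38, the assembly called mm10) by Ensembl identifier, which gave a symbol and coordinates for 21745 genes. The remaining 420 genes held 0.129% of the counts and stayed in the test. No count was present in any library for 6866 genes. Total counts ranged from 5554288 to 15680671 per library. Libraries of a group differed by more than the counting error of independent reads, with a chi-square per degree of freedom of 16.1 to 47.9 summed over genes. Repeated reads of a molecule also raise this value, so it cannot tell whether depth in molecules set the precision. Which genes were limited by counting error was not tested.

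Groups were taken from the labels' genotype and treatment. Genes were filtered with edgeR's filterByExpr by group (minimum count 10), which left 11079 genes, and library sizes were scaled by TMM. Differences were tested with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood F-test in a fit of all 8 libraries with 1 mean per group, so that the groups share an estimate of the spread. Benjamini-Hochberg adjusted p-values under 0.05 were called, with no fold threshold. The comparisons were DI against untreated in wild type and in knockout, the interaction of both factors, and knockout against wild type in untreated and in DI-treated cells. CPM values were computed from the deposited counts and the scaled library sizes. Standard errors of log2 fold changes are those of the fitted model. Folds against a group without counts were computed against a floor of 3 counts over the group, and ratios with 1 to 3 counts in a group have 95% counting intervals.

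Of 24 gene lists fixed before the data were examined, 23 were tested with limma 3.58.1 (camera with a preset correlation of 0.01 between genes, and fry) on log2 CPM with a prior count of 2, adjusted over the lists of a comparison. The lists hold the genes the series is about, NRF2 targets, the integrated stress response, chaperones of the endoplasmic reticulum, cytosolic heat shock proteins, inflammatory genes, interferon-stimulated genes, cholesterol synthesis, sterol efflux, cell cycle, lysosome and autophagy, macrophage identity, alternative activation, MHC class II, glycolysis, p53 targets, mitochondrial transcripts and ribosomal proteins. Markers of neutrophils, dendritic cells, lymphocytes, mast cells and basophils, erythroid cells and stromal cells stand for other cell types of bone marrow. Members called are counted over all genes tested and also adjusted over the list alone. Only the camera calls of the NRF2 targets in wild-type DI cells and in knockout against wild-type DI cells, and of the heat shock, integrated stress response and interferon lists in knockout DI cells, hold with an estimated correlation.

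The rule for named genes, fixed before the data were examined, took per comparison the 8 called genes with the largest increase and the 8 with the largest decrease, with a mean of at least 10 CPM in the higher group and libraries that do not overlap. For the interaction it took the 8 genes with the smallest p in each direction. It added up to 4 members with the smallest p of each list in each DI comparison and all genes the series is about. Predicted gene models without a proper symbol were passed over. Other genes named as examples of a list or comparison were chosen after their values were seen.

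The highest number of A in any 15 consecutive bases of the coding sequence was computed from the longest coding transcript of each gene in the GENCODE basic set, for 10999 tested genes. This property was examined only after the data were seen. To remove its trend, the median deviation of log2 CPM per class of A count was entered per library as an offset. The steps were tested on simulated data drawn from the means and library sizes of these libraries with 200 genes changed. The changed genes all had a mean above 10 CPM. Each gene was given the spread of the fitted trend at its level, with no spread of its own. For the comparison of DI in wild type (10889 genes), 45% of changes of 2-fold and 100% of 4-fold were recovered, with 2.68% false calls. For the interaction (10892 genes), 16% of 2-fold and 89% of 4-fold changes were recovered, with 4.55% false calls. In a simulation of the A trend for the interaction (10911 genes), 85% of 4-fold changes were recovered with and without the offset, while false calls fell from 21 to 5. The simulated trend followed the same A classes that the offset removes, with slopes near those of these libraries. It therefore checks the computation and not whether the offset suits the real trend.

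Alternatives fixed before the data were examined were DESeq2 1.42.0, median-of-ratios factors, no count filter, a fit of the 4 libraries of a comparison alone, the replicate number as a block, leaving out each library in turn, an estimated correlation and a smaller prior count for the lists, and, for the similarity of both responses, only genes of at least 10 CPM. With 2 libraries per group, other splits of the libraries and tests for outlying libraries were not run. Erythroid markers and Il6 had too few counts for the test.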

Results

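Gene expression was measured in bone marrow-derived macrophages of C57BL/6 mice, which are bone marrow cells grown into macrophages for 7 days with the growth factor M-CSF. The design crossed genotype with treatment. Cells were wild type or lacked NRF2, the transcription factor that drives antioxidant gene expression, and were left untreated or given 250 µM dimethyl itaconate (DI), a membrane-permeable electrophilic itaconate derivative, for 12 h. The series title names electrophilic stress and inflammation mediated by IκBζ, the protein product of Nfkbiz. Each of the 4 groups had 2 libraries of poly(A) RNA read near transcript 3′ ends. The deposited counts summed to 11217220 and 15680671 in the wild-type untreated libraries and to 6739038 and 11391531 in the wild-type DI libraries. They summed to 5554288 and 8788613 in the knockout untreated libraries and to 9310605 and 9637572 in the knockout DI libraries. Between 12418 and 13481 genes had at least 1 count per library. The labels do not say that the 2 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Levels are in CPM, counts scaled by the TMM-adjusted library size, given as mean ± SD with n = 2, and changes are log2 fold changes ± standard error. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 11079 genes.

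The targeted gene, Nfe2l2 (ENSMUSG00000015839), lies on the minus strand of chromosome 2 at 75675513 to 75704641 of mm10. It had 2636 and 7022 counts in the wild-type untreated libraries and 1901 and 4469 in the wild-type DI libraries. The knockout libraries held 230 and 488 counts when untreated and 634 and 869 with DI. Nfe2l2 fell to 46.6 ± 9.0 CPM in untreated knockout cells from 342 ± 158 CPM in untreated wild type, a log2 fold change of -2.87 ± 0.34 with edgeR adjusted p = 0.0019. That call was lost without knockout untreated replicate 1, where the change was -2.69 and the edgeR adjusted p was 0.0884. In DI the difference was -2.20 ± 0.33 with edgeR adjusted p = 0.000784. The counted 3′ tags may or may not lie in the deleted part of the gene, so the remaining counts check the deletion only weakly. Among 134 tested genes within 20 megabases of Nfe2l2 on the chromosome, only Nfe2l2 itself passed the test in untreated cells. In a principal component analysis the first component held 44.9% of the variance and separated the wild-type DI libraries from the other 6. The second component held 20.9% and separated the knockout DI libraries from the untreated knockout libraries. The 2 libraries of a group correlated at r = 0.973 to 0.980 across genes.

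**Figure D1:**
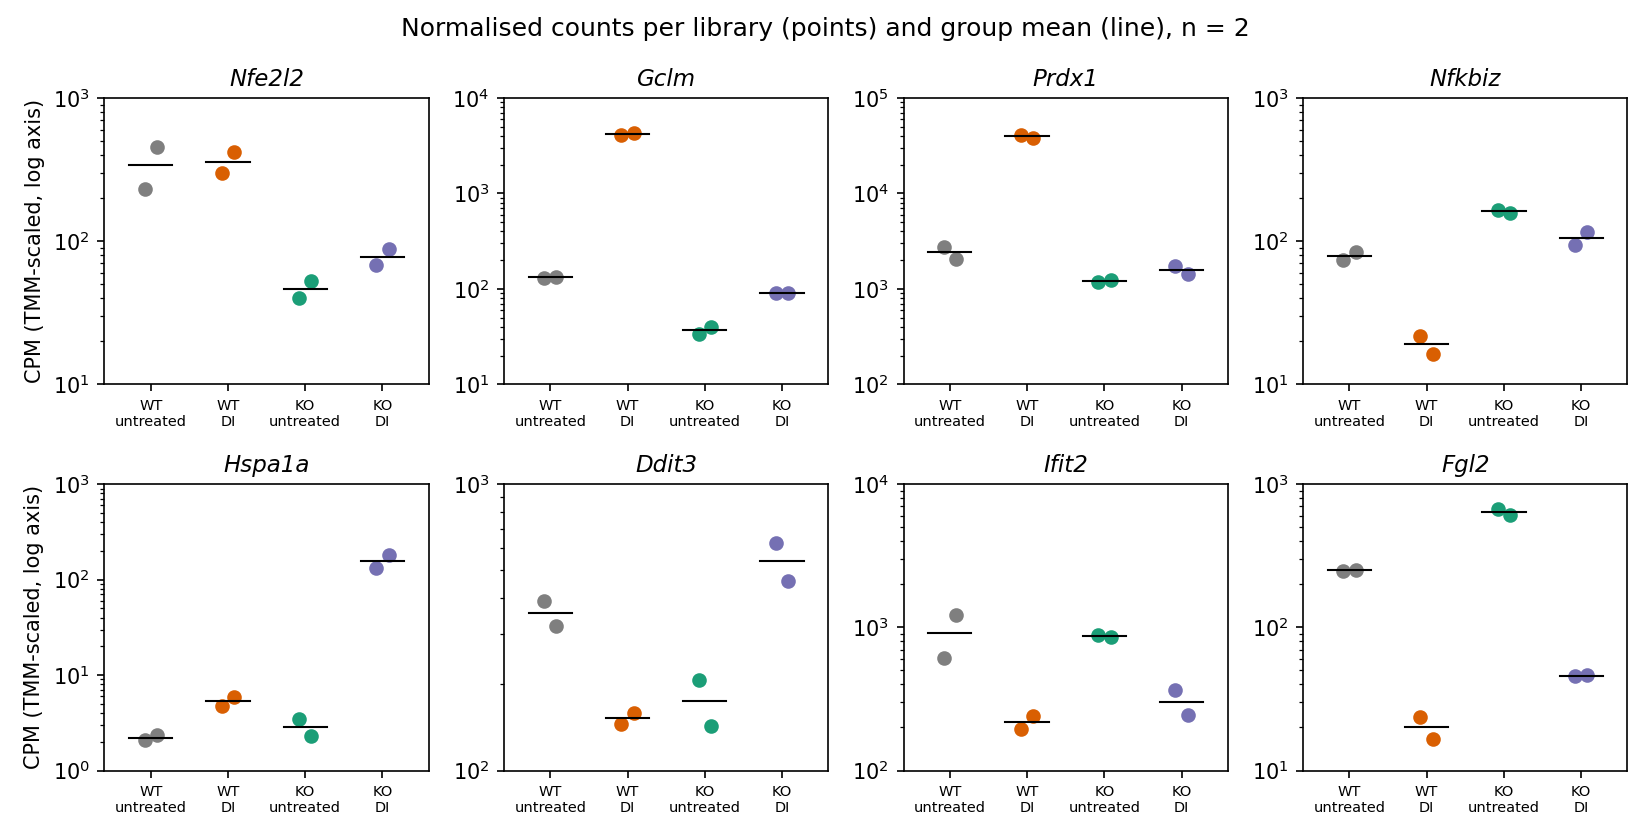
CPM of Nfe2l2, Gclm, Prdx1, Nfkbiz, Hspa1a, Ddit3, Ifit2 and Fgl2 in each of the 8 libraries, on a log axis, by genotype and treatment; points are libraries and lines are group means. Gclm averaged 4213 CPM in wild-type DI libraries and 90.8 CPM in knockout DI libraries, while Hspa1a averaged 5.29 and 156 CPM in the same groups.

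In wild-type macrophages DI raised Gclm, Gclc and Prdx1, which serve glutathione synthesis and peroxide removal, and lowered Nfkbiz. Gclm, the modifier subunit of glutamate-cysteine ligase (chromosome 3, 122245557 to 122270732), rose 31.9-fold from 132 ± 3.10 to 4213 ± 104 CPM, a log2 change of 5.0 ± 0.24 with edgeR adjusted p = 6.94e-07. Its catalytic partner Gclc rose by 4.38 ± 0.27 and the cystine transporter Slc7a11 by 4.96 ± 0.31 on the log2 scale. Prdx1, a peroxiredoxin, rose from 2418 ± 495 to 39516 ± 1743 CPM. The 10 most abundant genes took 12.9 to 13% of counts in the wild-type DI libraries and 7.20 to 8.76% in the other 6. Nfkbiz (chromosome 16, 55811375 to 55838899) fell from 79.1 ± 7.34 to 19.1 ± 3.91 CPM, a log2 change of -2.06 ± 0.24 with edgeR adjusted p = 0.000193.

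Among called genes with a proper symbol, a mean of 10 CPM or more in the higher group and libraries that did not overlap, the largest increases in wild-type cells were those of Gsta3, a glutathione transferase, at 6.98 ± 0.50 on the log2 scale, Serpinb9b at 5.94, Tarm1 at 5.88, Dnmt3l at 5.44, the endothelin receptor Ednrb at 5.35 and the quinone reductase Nqo1 at 5.34. Procr, the protein C receptor, rose by 5.32 and the neutrophil-attracting chemokine Cxcl3 by 5.29. The largest decreases among the same genes were those of Tnfsf8, the CD30 ligand, at -5.13 ± 0.47, Lrrc4 at -4.74, the sialyltransferase St3gal6 at -4.36, the endothelial lipase Lipg at -4.30 and BC147527 at -4.18. Fgl2, a fibrinogen-like protein, fell by 3.65, the histone deacetylase Hdac9 by 3.57 and Pcp4l1 by 3.57. Gsta3, Tarm1 and Dnmt3l had only 8, 11 and 6 counts over both wild-type untreated libraries, so the sizes of their increases are uncertain. Hmox1, heme oxygenase, rose by 2.86 ± 0.25. Acod1, which encodes the enzyme that makes itaconate, differed by 0.72 ± 0.24 with edgeR adjusted p = 0.0627, Atf3 by 0.89 ± 0.29 with adjusted p = 0.0585 and Keap1 by 0.82 ± 0.28 with adjusted p = 0.0655. None of these 3 passed in edgeR over all genes, while DESeq2 called all 3 higher, as did edgeR adjusted over the genes the series is about. Il6 had 0 to 5 counts per library and was not tested.

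By group, 27 of 30 tested NRF2 target genes rose in wild-type DI cells (27 adjusted over the list alone), with a median log2 change of 2.71. The camera adjusted p was 3.67e-30, and adjusted p = 0.0354 with an estimated correlation. Of 26 interferon-stimulated genes, 13 fell (16 adjusted over the list alone), among them the antiviral genes Ifit2 at -2.07, Mx1 at -2.03, Gbp2 at -1.68 and Rsad2 at -1.38. Camera gave adjusted p = 1.39e-05, and adjusted p = 0.0696 with an estimated correlation. Of 28 genes of DNA replication and mitosis, 7 fell (8 adjusted over the list alone), with the mitotic kinesin Kif11 at -2.51 and the replication helicase subunit Mcm4 at -1.48 (camera adjusted p = 5.66e-05; adjusted p = 0.107 with an estimated correlation). Of 21 glycolysis genes, 7 rose (9, and 1 lower, adjusted over the list alone), including pyruvate kinase Pkm at 1.76 and the glucose transporter Slc2a1 at 1.68 (camera adjusted p = 0.000394; adjusted p = 0.198 with an estimated correlation). Of 14 cytosolic heat shock genes, 5 rose (8, and 1 lower, adjusted over the list alone), with Hspa1b at 1.61 and Hspa1a at 1.26 (camera adjusted p = 0.00364; adjusted p = 0.198 with an estimated correlation). Of 27 inflammatory genes, 4 rose and 7 fell (7 and 10 adjusted over the list alone). The cyclooxygenase gene Ptgs2 rose by 2.58 and the NF-κB inhibitor Tnfaip3 by 1.62, whereas the chemokine Ccl7 fell by 2.04 (camera adjusted p = 0.531). Of 20 macrophage identity genes, 7 fell (7 lower and 1 higher adjusted over the list alone), with the fractalkine receptor Cx3cr1 at -3.52, the transcription factor Maf at -2.29 and the lipopolysaccharide co-receptor Cd14 at -1.68 (camera adjusted p = 0.0579). Without wild-type DI replicate 1, 8 interferon and 4 cell cycle genes fell, and 1 inflammatory gene rose and 2 fell. Without wild-type DI replicate 2, 8 interferon genes fell, 3 heat shock genes rose, and 2 inflammatory genes rose and 2 fell, and Hspa1a had adjusted p = 0.102. Without wild-type untreated replicate 1, 2 inflammatory genes rose and 4 fell. The call of Hspa1a was also lost without either wild-type untreated library. Without wild-type untreated replicate 2, 4 glycolysis genes, 1 heat shock gene and 2 inflammatory genes rose, 4 macrophage genes fell and Tnfaip3 had adjusted p = 0.0861. With the trend for A-rich coding sequence described below removed, 2 inflammatory genes rose and the macrophage list had camera adjusted p = 0.00951.

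Further lists were tested in wild-type cells. Of 17 endoplasmic reticulum chaperone genes, 5 rose (5 adjusted over the list alone), led by Manf at 1.21 (camera adjusted p = 0.127). Their count was 2 and 1 without wild-type untreated replicates 1 and 2, 3 without either wild-type DI library and 2 without knockout untreated replicate 2. Of 25 lysosome and autophagy genes, 4 rose and 1 fell, with the autophagy receptor Sqstm1 at 2.13 (camera adjusted p = 0.162). The rising genes numbered 1 without wild-type untreated replicate 1 and 2 without wild-type untreated replicate 2 or either knockout untreated library. Of 28 integrated stress response genes, 1 rose and 2 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.291). The falling genes were the transcription regulators Nupr1 at -1.77 and Ddit3 at -1.22. Ddit3 lost its call without wild-type untreated replicate 1, where its change was -1.08. The rising gene, Ppp1r15a at 0.78, lost its call in 6 of 8 fits without 1 library, among them those without each untreated library. Of 16 p53 target genes, 2 rose, including the stress cytokine Gdf15 at 1.97, and Sesn1 fell by 1.89 (2 and 2 adjusted over the list alone; camera adjusted p = 0.769; 1 rose without either wild-type untreated library or wild-type DI replicate 1). Of 9 alternative activation genes, the lectin Clec10a rose by 1.79 and 2 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.379; neither of the 2 was called without either wild-type DI library or without wild-type untreated replicate 2). For 23 cholesterol genes camera gave adjusted p = 0.657. Among 10 sterol efflux genes Mylip rose by 1.52 and the nuclear receptor Nr1h3 fell by 1.14 (camera adjusted p = 0.769). Among 34 ribosomal protein genes Rpl23 rose by 0.68, a call lost without any 1 of the 8 libraries and when adjusted over the list alone (camera adjusted p = 0.0255, direction up; adjusted p = 0.422 with an estimated correlation). Of 13 transcripts of the mitochondrial genome, a sign of RNA and cell quality, 5 rose, with mt-Co3 at 1.14 (6, and 1 lower, adjusted over the list alone; camera adjusted p = 0.0255; adjusted p = 0.422 with an estimated correlation). Without wild-type untreated replicate 1, 1 of these transcripts passed, without wild-type DI replicate 2, 2 passed, and without wild-type untreated replicate 2 none rose and 1 fell, with mt-Co3 at adjusted p = 0.059. The mitochondrial share of counts was 1.30 and 1.37% in wild-type untreated libraries and 1.59 and 2.10% in wild-type DI libraries. Removing the A-rich sequence trend left 3 ribosomal and 2 integrated stress response genes rising, 2 p53 genes falling and 0 lysosome genes falling. No MHC class II gene of 8 was called by edgeR, with 3 at an unadjusted p under 0.05 and 1 by DESeq2 (camera adjusted p = 0.165). Fry differed from camera for some of these lists. It gave adjusted p = 0.121 for mitochondrial and 0.0961 for ribosomal genes, which did not pass. Its adjusted p was 0.0204 for lysosome, 0.0441 for endoplasmic reticulum chaperone and 0.0256 for MHC class II genes.

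The edgeR test called 721 genes higher and 962 lower in wild-type DI cells (1683 in all; DESeq2 called 742 and 1017). These counts were 391 and 662 without wild-type untreated replicate 1, 290 and 514 without replicate 2, 495 and 506 without wild-type DI replicate 1, and 471 and 571 without replicate 2. Of 73 named calls in this comparison, 47 were kept without each library in turn. With the trend for A-rich coding sequence removed, 684 were higher and 840 lower, so 44.9% of calls were higher against 42.8%. Tested alone, genes whose coding sequence has at most 9 A in any 15 bases, an alternative added after the data were seen, gave 397 higher and 249 lower.

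In knockout macrophages DI raised Hspa1a, Hspa8 and Ppp1r15a and lowered Fgl2. Hspa1a, an inducible HSP70 gene on chromosome 17 at 34969190 to 34972156, rose 55.4-fold from 2.89 ± 0.86 to 156 ± 34.5 CPM, a log2 change of 5.79 ± 0.32 with edgeR adjusted p = 1.58e-06. Its near-identical neighbour Hspa1b rose by 5.74 ± 0.32, although how reads were divided between these copies is uncertain. Hspa8, the constitutive HSP70, rose by 2.37 ± 0.26 and Ppp1r15a, a phosphatase subunit that reverses eIF2α phosphorylation, by 2.25 ± 0.24. Fgl2 (chromosome 5, 21372642 to 21378374) fell from 641 ± 43.0 to 45.8 ± 0.52 CPM, a log2 change of -3.81 ± 0.25 with edgeR adjusted p = 8.43e-06.

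Other large increases in knockout cells were those of the zinc-finger gene Plagl1 at 3.65, Noxred1 at 2.49, the chemokine Cxcl2 at 2.40, the thioredoxin reductase Txnrd1 at 2.30 and Plcxd2 at 2.26. Among called genes with a proper symbol, at least 10 CPM in the higher group and libraries that did not overlap, the largest decreases after Fgl2 were those of Ifit1bl1 at -2.68, BC147527 at -2.62, the nuclear receptor Nr4a1 at -2.43, the phospholipase receptor Pla2r1 at -2.41, the chemokine Cxcl11 at -2.32, Nxpe5 at -2.27 and the class I gene H2-Q6 at -2.27. Ifit1bl1 and H2-Q6 belong to multigene families, so their counts may hold reads from related genes. Txnrd1 and Cxcl11 lost their calls without knockout untreated replicate 1 (adjusted p = 0.0616) and replicate 2 (adjusted p = 0.0649), respectively. Hmox1 rose by 2.19 ± 0.26 with edgeR adjusted p = 0.00132. Nqo1 had no counts in untreated knockout libraries and was at least 4.14-fold higher with DI, taking a floor of 3 counts over the group, and its edgeR adjusted p of 0.0255 became 0.171 without knockout untreated replicate 2. Acod1 fell by 1.23 ± 0.25 with edgeR adjusted p = 0.014, which became 0.125 without knockout untreated replicate 1. Nfkbiz differed by -0.63 ± 0.23 and did not pass the test over all genes (edgeR adjusted p = 0.105) or in DESeq2, but passed adjusted over the genes the series is about.

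By group, 12 of 14 heat shock genes rose in knockout DI cells (12 adjusted over the list alone), with a median log2 change of 1.42. Camera gave adjusted p = 1.42e-11, and adjusted p = 0.0292 with an estimated correlation. Of 28 integrated stress response genes, 11 rose (14, and 1 lower, adjusted over the list alone), including the transcription factor Ddit3 at 1.63, the pseudokinase Trib3 at 1.54 and the amino acid transporter Slc7a5 at 1.29. Camera gave adjusted p = 5.74e-07 and again adjusted p = 0.0292 with an estimated correlation. Of 26 interferon-stimulated genes, 11 fell (18 adjusted over the list alone), among them Ifit3 at -1.74, Ifit2 at -1.52, the chemokine Cxcl10 at -1.37 and Rsad2 at -1.17 (camera adjusted p = 1.26e-08; adjusted p = 0.0292 with an estimated correlation). Of 30 NRF2 target genes, 9 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.48, or 0.38 with the members that had no counts placed at their bounds. Gclm rose by 1.30 ± 0.21 and the epoxide hydrolase Ephx1 fell by 2.34 (camera adjusted p = 0.00243; adjusted p = 0.28 with an estimated correlation). Of 20 macrophage identity genes, 7 fell (10 adjusted over the list alone), among them Cx3cr1 at -1.59, the complement gene C1qc at -0.99 and the M-CSF receptor Csf1r at -0.87 (camera adjusted p = 0.000239; adjusted p = 0.259 with an estimated correlation). Without knockout untreated replicate 1, 3 heat shock, 3 integrated stress response, 2 interferon and 1 NRF2 target genes passed in these directions, and Gclm had adjusted p = 0.0971, Ephx1 0.0736, Slc7a5 0.117 and Ifit2 0.108. Without knockout untreated replicate 2 the counts were 3, 3, 3 and 3, Ddit3 had adjusted p = 0.0694, Rsad2 0.0995, C1qc 0.18 and Csf1r 0.229. Without knockout DI replicate 1 the counts were 4, 7, 5 and 4 and Cx3cr1 had adjusted p = 0.127. Of the macrophage genes, 2 and 3 fell without wild-type untreated replicates 1 and 2, and edgeR called 0 without knockout untreated replicate 1, knockout untreated replicate 2 or knockout DI replicate 1, with 9, 10 and 11 at an unadjusted p under 0.05. Once the trend for A-rich coding sequence described below was removed, 3 macrophage genes fell.

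Other lists were also tested in knockout cells. Of 16 p53 target genes, 2 rose and 4 fell (2 and 8 adjusted over the list alone), with Gdf15 at 1.39 and the cyclin gene Ccng1 at -1.36 (camera adjusted p = 0.00445; adjusted p = 0.28 with an estimated correlation). Both genes had adjusted p = 0.117 without knockout untreated replicate 1, where edgeR called none of the list and 9 had an unadjusted p under 0.05. Without knockout untreated replicate 2, 1 p53 gene rose and 1 fell, without knockout DI replicate 1, 1 rose and none fell, and without knockout DI replicate 2, 1 rose and 3 fell. With the A-rich sequence trend removed, 1 p53 gene rose and 1 fell. Of 8 MHC class II genes, H2-DMb1 fell by 1.51 and H2-DMa by 1.25 (6 adjusted over the list alone; camera adjusted p = 0.0035; adjusted p = 0.152 with an estimated correlation). Their adjusted p-values were 0.175 without knockout untreated replicate 1 and 0.188 without knockout DI replicate 1, respectively, and neither was called with that trend removed. Of 27 inflammatory genes, Cxcl2 and Ptgs2 rose, the latter by 1.02, and Tlr2, a receptor for bacterial lipopeptides, and Acod1 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.58). Ptgs2 had adjusted p = 0.222, Tlr2 0.14 and Acod1 0.125 without knockout untreated replicate 1. Without either knockout untreated library or knockout DI replicate 1, 1 inflammatory gene rose and none fell, whereas 3 rose and 5 fell without either wild-type DI library. The cell cycle genes had no edgeR call among 28, with 4 at an unadjusted p under 0.05 and none by DESeq2 (camera adjusted p = 0.574). The mitochondrial transcripts had no call among 13, with 0 at an unadjusted p under 0.05 and none by DESeq2 (camera adjusted p = 0.715). The mitochondrial share of counts was 1.42 and 1.49% in untreated and 1.02 and 1.54% in DI-treated knockout libraries. Camera gave adjusted p = 0.464 for glycolysis genes, 0.464 for lysosome genes, 0.189 for chaperones of the endoplasmic reticulum, 0.661 for ribosomal proteins, 0.768 for cholesterol genes, 0.49 for sterol efflux genes and 0.715 for alternative activation genes.

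The edgeR test called 497 genes higher and 443 lower in knockout DI cells (DESeq2 called 701 and 522). The counts were 29 and 75 without knockout untreated replicate 1, 37 and 74 without replicate 2, and 145 and 108 without knockout DI replicate 1. Of 50 named calls, 19 were kept without each library in turn, among them Hspa1a, Hspa1b, Hspa8, Fgl2, Ppp1r15a, Trib3, Ifit3, Cxcl10, Cxcl2, Plagl1 and Hmox1. With the A-rich sequence trend removed the counts were 375 and 375, and among genes with at most 9 A in any 15 coding bases they were 110 and 213.

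The test of the difference between genotypes asked which DI effects depended on NRF2. The interaction was negative for Gclm and Prdx1 and positive for Hspa1a and for Ddit3 (chromosome 10, 127290774 to 127296288), a transcription factor of the stress response. The interaction term, the log2 change in knockout minus that in wild type, was -3.69 ± 0.30 for Gclm, -3.64 ± 0.33 for Prdx1, 4.53 ± 0.44 for Hspa1a and 2.85 ± 0.36 for Ddit3, with edgeR adjusted p-values of 0.00022, 0.000226, 0.000283 and 0.00139. Ddit3 went from 355 ± 49.1 to 152 ± 9.19 CPM in wild type and from 175 ± 44.7 to 540 ± 117 CPM in knockout cells. Nfkbiz had an interaction of 1.43 ± 0.33 with edgeR adjusted p = 0.0233, a call lost without wild-type untreated replicate 2, wild-type DI replicate 2 or either knockout untreated library (up to 0.0992 without knockout untreated replicate 2). Acod1 (chromosome 14, 103046977 to 103056573) had an interaction of -1.96 ± 0.35 with edgeR adjusted p = 0.00713.

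The other genes with the smallest interaction p-values and a lower response in the knockout were Ptgr1, a reductase of prostaglandins and other electrophiles, at -4.49 ± 0.38, catalase (Cat) at -3.91, cytochrome b5 (Cyb5a) at -3.79, glutathione synthetase (Gss) at -3.65, Gclc at -3.58 and the fungal-sensing lectin receptor Clec4n at -3.54. Those with a higher response were Uaca at 4.20 ± 0.52, Hspa1b at 4.14, the nuclear phosphoprotein Anp32a at 3.38, the vesicle protein Vti1b at 3.07, Sdccag8 at 2.95 and the helicase Dhx40 at 2.72. Anp32a, Vti1b, Sdccag8 and Dhx40 have 11 or 12 A in 15 coding bases. Hmox1 had an interaction of -0.67 ± 0.35 with edgeR adjusted p = 0.24, Keap1 of -0.72 ± 0.39 with adjusted p = 0.26 and Atf3 of 0.03 ± 0.41 with adjusted p = 0.969. Nqo1 had no counts in untreated knockout libraries, so its fitted interaction has no meaningful size or sign.

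By group, 19 of 30 NRF2 target genes had a negative interaction that passed (21 adjusted over the list alone), with a median interaction of -2.28, or -2.26 without the 3 members that had a group without counts (camera adjusted p = 6.97e-21; adjusted p = 0.0713 with an estimated correlation). Of 14 heat shock genes, 5 had a positive interaction (7 adjusted over the list alone), with a median of 1.20 and Hspa8 at 1.62 (camera adjusted p = 0.000697; adjusted p = 0.217 with an estimated correlation). Of 28 integrated stress response genes, 7 had a positive interaction (7 adjusted over the list alone), among them Ddit3, Nupr1 at 2.12, Ppp1r15a at 1.47 and Trib3 at 1.19 (camera adjusted p = 0.0082; adjusted p = 0.217 with an estimated correlation). Of 28 cell cycle genes, 5 had a higher response (6 adjusted over the list alone), including Ccne2 at 2.13 and Kif11 at 1.68 (camera adjusted p = 0.0102; adjusted p = 0.25 with an estimated correlation). Both have 12 A in 15 coding bases, and 1 cell cycle gene passed once the trend with A-rich coding sequence was removed. The list median was then 0.665 against 0.674 before, and camera still passed (adjusted p = 0.0131 with the preset correlation). Of 26 interferon-stimulated genes, 1 passed, Ifih1 at 2.46, named here after its value was seen, and the list median was -0.01 (camera adjusted p = 0.865; Ifih1 was not called without knockout untreated replicate 2). Of 27 inflammatory genes, 3 had a higher response, including Ccl7 at 1.60, and 3 a lower one, including Tnfaip3 at -2.31 and Ptgs2 at -1.56 (camera adjusted p = 0.869). Without knockout untreated replicate 1, 2 heat shock, 3 integrated stress response, 1 higher inflammatory and no cell cycle genes passed in edgeR, with 8 cell cycle genes at an unadjusted p under 0.05. The counts were 3 heat shock, 2 integrated stress response and 1 cell cycle genes without knockout untreated replicate 2. Without wild-type untreated replicate 1, 3 cell cycle genes passed. Without wild-type untreated replicate 2 the counts were 4 integrated stress response and 1 cell cycle genes, without wild-type DI replicate 1 they were 4 and 2, and 1 cell cycle gene passed without knockout DI replicate 1. The lower inflammatory genes numbered 1 without wild-type untreated replicate 2, wild-type DI replicate 1 or knockout untreated replicate 2.

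For the remaining lists camera, which tests for a shared direction, gave adjusted p-values just under the threshold or above it. Camera gave adjusted p = 0.0444 for glycolysis genes (3 of 21 with a negative interaction, among them Pkm at -1.73 and Slc2a1 at -1.48), 0.0444 for p53 targets, 0.0444 for mitochondrial transcripts (mt-Co3 at -1.20), 0.0444 for ribosomal proteins and 0.0493 for lysosome genes, all in the direction down. Adjusted over the list alone, 5 glycolysis, 5 p53 and 5 mitochondrial genes had a negative interaction and 0 lysosome genes did. The ribosomal list had 1 gene with a positive and 0 with a negative interaction, both over all genes and over the list alone. With an estimated correlation the 5 camera results became adjusted p = 0.423, 0.423, 0.586, 0.586 and 0.275. Fry gave adjusted p = 0.218 for mitochondrial and 0.139 for ribosomal genes, which did not pass. Its adjusted p was 0.0302 for each of the glycolysis, p53 and lysosome lists and 0.0344 for MHC class II genes. Removing the trend for A-rich coding sequence gave glycolysis, p53, ribosomal and lysosome lists camera adjusted p = 0.257, 0.115, 0.21 and 0.0748, while mitochondrial transcripts still passed at 0.0282. The list medians were then -0.319 for glycolysis (-0.362 before), -0.361 for p53 (-0.560), -0.245 for ribosomal (-0.350), -0.302 for lysosome (-0.285) and -0.778 for mitochondrial genes (-0.680). The glycolysis count was 1 without wild-type untreated replicate 2. The negative mitochondrial call was lost without either wild-type untreated library, wild-type DI replicate 2, either knockout untreated library or knockout DI replicate 1. More mitochondrial transcripts passed with a negative interaction without wild-type DI replicate 1 or knockout DI replicate 2. Camera gave adjusted p = 0.344 for MHC class II genes, 0.712 for macrophage identity, 0.869 for cholesterol genes, 0.477 for sterol efflux, 0.758 for alternative activation and 0.869 for chaperones of the endoplasmic reticulum. Adjusted over the list alone, 4 of these chaperone genes had a positive and 5 a negative interaction, as had 2 and 2 macrophage genes, 0 and 2 sterol efflux genes and 1 and 0 alternative activation genes.

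The edgeR interaction test called 549 genes higher and 287 lower in knockout than in wild-type response (DESeq2 called 773 and 412). Of the 549, 255 were called for DI in wild type alone, 139 in knockout alone, 69 in both and 86 in neither, and for the 287 these numbers were 196, 50, 14 and 27. Both genotypes shared 76 raised genes against 32.3 for independent lists and 173 lowered genes against 38.5 (Fisher's exact test p = 1.29e-12 and 1.78e-72 across genes). That test takes genes as independent, which they are not, so its p-values do not measure how firm the sharing is. Of 721 genes raised in wild type, 210 (29.1%) had a called interaction against the direction of their wild-type change, as did 321 of 962 lowered genes (33.4%), while 6 and 58 genes were called in opposite directions. Across 11079 genes, which are not independent replicates, the slope of the knockout on the wild-type response was 0.17 with Pearson r = 0.20 and Spearman rho = 0.13. Without wild-type DI replicate 2 the slope was 0.081 and r was 0.11. The call counts without 1 library ranged from 137 and 101 without knockout untreated replicate 1, through 162 and 108 without replicate 2, 246 and 119 without wild-type untreated replicate 2, 265 and 186 without wild-type DI replicate 1, 308 and 143 without knockout DI replicate 1 and 441 and 190 without wild-type untreated replicate 1, up to 609 and 324 without knockout DI replicate 2.

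**Figure D2:**
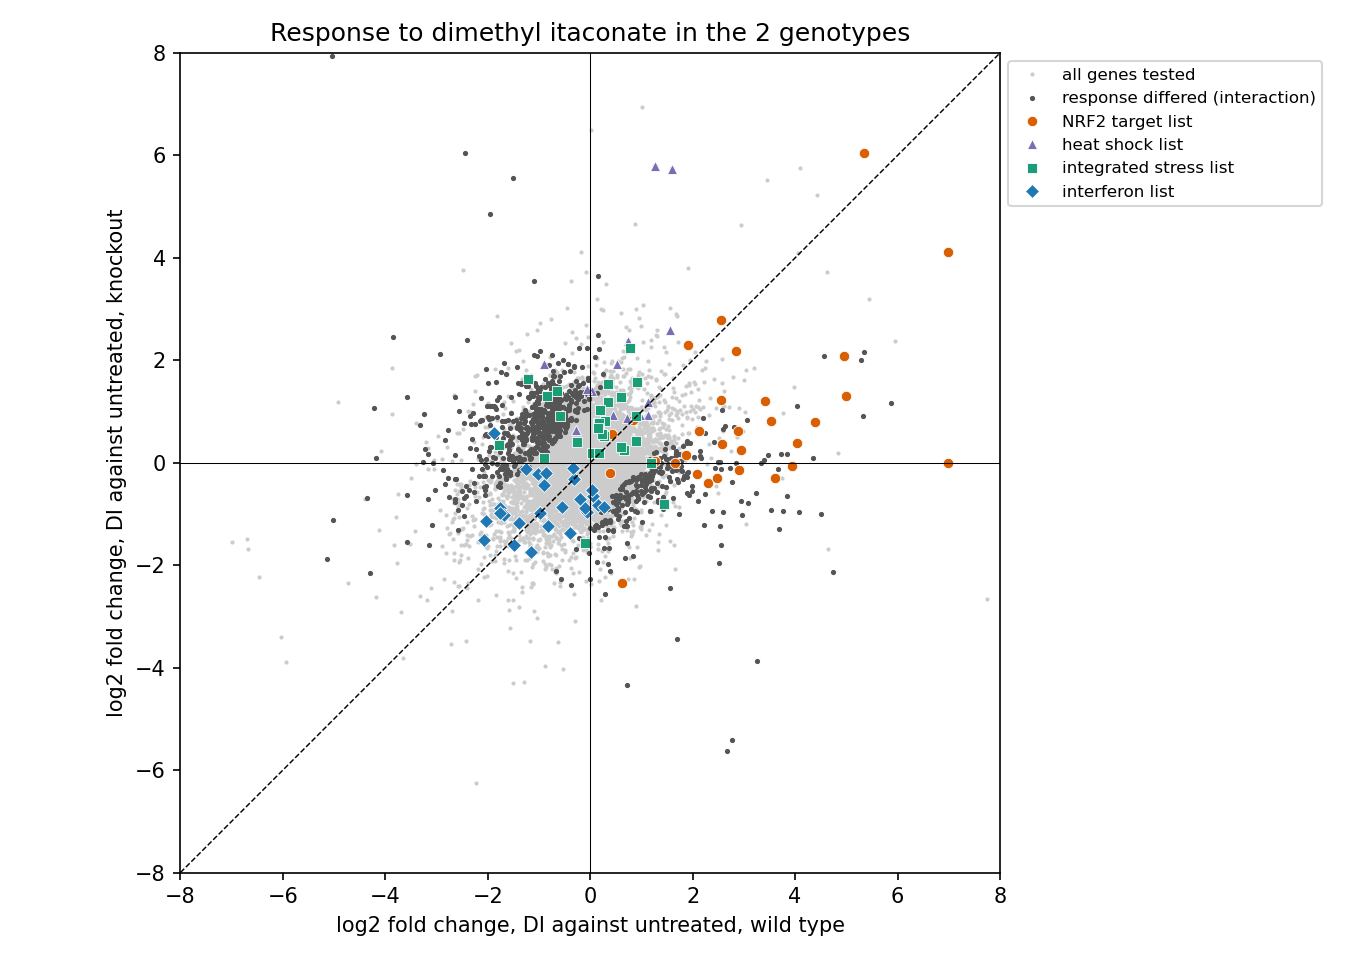
Log2 fold change of each of 11079 tested genes with dimethyl itaconate in wild-type cells (horizontal axis) and in knockout cells (vertical axis); dark points passed the interaction test, coloured points are members of the NRF2 target, heat shock, integrated stress response and interferon lists, and the dashed line marks equal responses. Of 30 NRF2 target genes 19 passed with a negative interaction, and of 14 heat shock genes 5 passed with a positive one. The positions of Nqo1, Gsta3 and Gsta4, each with a group without counts, have no meaningful size.

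The direction of the interaction calls followed the A content of the coding sequence. Among 3231 genes with at least 11 A in some 15 coding bases, 323 (10%) were called higher and 26 (0.805%) lower. Among 4776 genes with at most 9 A the figures were 91 (1.91%) and 180 (3.77%). The highest A count in 15 bases and the interaction correlated at Spearman rho = 0.36 across 10999 genes. With this trend removed per library, a step added after the data were seen, 373 genes were higher and 246 lower, and 61.1% of the calls were shared. Tested on the genes with at most 9 A alone, 77 were higher and 146 lower, so 34.5% of calls were higher instead of 65.7%. These genes lie at the low end of the A trend, with a median interaction of -0.30. An excess of lower calls is therefore expected from their selection and does not give the split without the trend. The 18 interaction calls taken by the rule for named genes kept their direction and call with the trend removed, whereas called cell cycle genes fell in number from 5 to 1 and the call of a mitochondrial transcript was lost. The list medians stayed similar, at 0.665 against 0.674 before for cell cycle genes and -0.778 against -0.680 for mitochondrial transcripts. Camera with the preset correlation still passed for both lists (adjusted p = 0.0131 and 0.0282).

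**Figure D3:**
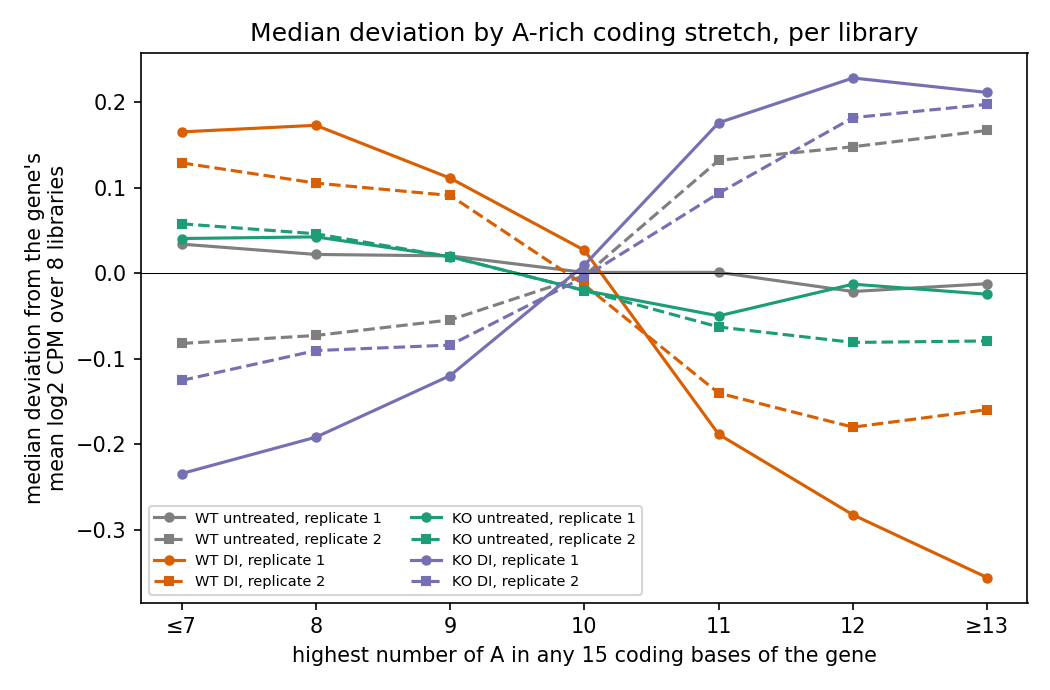
Median deviation of log2 CPM from each gene's mean over the 8 libraries (vertical axis) against the highest number of A in any 15 coding bases, in classes from 7 or fewer to 13 or more (horizontal axis); each line is a library, coloured by group. The lines of the wild-type DI libraries fell with A content (slopes of -0.10 and -0.07 log2 per A) and those of the knockout DI libraries rose (0.09 and 0.06). Slopes were -0.0049 and 0.056 in the wild-type untreated libraries and -0.012 and -0.023 in the knockout untreated libraries.

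Without treatment, knockout macrophages had lower levels of a small set of genes. Npy, neuropeptide Y, fell from 209 ± 31.1 to 0.61 ± 0.87 CPM, the iron exporter Slc40a1 from 141 ± 44.0 to 10.5 ± 3.92 CPM and Ifi208, of the interferon-inducible p200 family, from 71.0 ± 26.0 to 2.06 ± 1.54 CPM. Their log2 changes were -8.71 ± 0.84, -3.72 ± 0.33 and -5.22 ± 0.44 with edgeR adjusted p-values of 0.000364, 0.000231 and 0.000231. The ubiquitin ligase Rnf128 fell by 2.94, the phospholipase Pla2g7 by 2.78, Tnfaip2 by 2.71 and the phosphodiesterase Pde1c by 2.88, the last with adjusted p = 0.0884 without knockout untreated replicate 1. Nqo1 was at least 11.7-fold lower, with 0 counts in both knockout libraries, and its edgeR adjusted p of 0.0117 became 0.127 without knockout untreated replicate 2. Ifi208 belongs to a gene family with similar members, so its counts may hold reads from relatives.

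Genes higher in untreated knockout cells included Pou5f2 at 2.01, Fcrls at 1.70, Tmem161b at 1.67, Wdfy1 at 1.65, Rnase4 at 1.42, Fgl2 at 1.35 and the formyl peptide receptor Fpr2 at 1.14. None of these 7 kept its call without every library, with highest adjusted p-values of 0.109 for Fcrls, 0.215 for Fgl2, 0.339 for Fpr2 and 0.23 for Wdfy1 without knockout untreated replicate 1, and of 0.129 for Pou5f2, 0.209 for Rnase4 and 0.0916 for Tmem161b without replicate 2. Nfkbiz differed by 1.03 ± 0.23 with edgeR adjusted p = 0.0715 and Hmox1 by -1.15 ± 0.25 with adjusted p = 0.0697, so neither passed in edgeR over all genes, while both were called by DESeq2 and by edgeR adjusted over the genes the series is about. Acod1, Atf3 and Keap1 differed by 0.04 ± 0.24, -0.30 ± 0.29 and -0.21 ± 0.28.

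Of 30 NRF2 target genes, 10 were lower in untreated knockout cells (20 adjusted over the list alone), among them Txnrd1 at -2.65, Slc7a11 at -2.17, Gclm at -1.84 and Gclc at -1.42. The list median was -0.99, or -0.91 with members lacking counts placed at their bounds (camera adjusted p = 2.21e-20; adjusted p = 0.0521 with an estimated correlation). Without wild-type untreated replicates 1 and 2 the count was 3 and 4, without knockout untreated replicate 2 it was 2, and without replicate 1 edgeR called 0, with 16 at an unadjusted p under 0.05. Of 9 stromal markers, genes typical of fibroblasts, 2 were lower (6 adjusted over the list alone; camera adjusted p = 3.67e-07; adjusted p = 0.0521 with an estimated correlation), the matrix genes Sparc at -1.49 and Col1a2 at -1.33, the latter named after its value was seen. Their median was -1.09, and edgeR called 0 of them without wild-type untreated replicate 2, where 6 had an unadjusted p under 0.05, or without either knockout untreated library, where 4 did. Of them, 1 was called without wild-type untreated replicate 1 or any of the DI libraries, and 1 with the A-rich sequence trend removed. The inflammatory and MHC class II lists each had camera adjusted p = 0.011 (up and down), with no edgeR call of 27 and 8 genes, 7 and 4 at an unadjusted p under 0.05, and 2 and 1 by DESeq2. Adjusted over the list alone, 4 inflammatory genes were higher and 1 lower, and 4 MHC class II genes were lower. With an estimated correlation these were adjusted p = 0.371 and 0.25. Fry gave adjusted p = 0.126 for the inflammatory list, which did not pass, and 0.0144 for the MHC class II list.

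In untreated cells edgeR called 9 genes higher and 58 lower in the knockout, with 1179 at an unadjusted p under 0.05, while DESeq2 called 34 and 142. Without knockout untreated replicate 1 the counts were 1 and 10, without replicate 2 they were 3 and 13, without wild-type untreated replicates 1 and 2 they were 2 and 24 and 3 and 45, and without wild-type DI replicates 1 and 2 they were 16 and 62 and 16 and 65.

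With DI, the genotypes differed in many more genes, and NRF2 targets were among the most strongly lowered. Nqo1 was at 95.6 ± 14.8 CPM in wild-type and 0.84 ± 0.62 CPM in knockout cells, a log2 difference of -6.82 ± 0.40 with edgeR adjusted p = 1.07e-06. Procr was 95.1-fold lower (-6.57 ± 0.36) and Ednrb 74.5-fold lower (-6.22 ± 0.38), with edgeR adjusted p-values of 5.82e-07 and 8.95e-07. Hspa1a was 29.2-fold higher in the knockout (4.87 ± 0.30, edgeR adjusted p = 8.95e-07). Nfkbiz was 5.50-fold higher, at 104 ± 15.1 against 19.1 ± 3.91 CPM (2.46 ± 0.25, edgeR adjusted p = 3.87e-05), and Acod1 was lower by a log2 difference of -1.92 ± 0.25 (edgeR adjusted p = 0.000328).

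The other large decreases were those of Gsta3 at -7.47, Npy at -7.34, the monocarboxylate transporter family gene Slc16a9 at -6.55 and the hyaluronan receptor Layn at -6.34. Gsta3 and Layn had only 4 and 9 counts over both knockout DI libraries. Dnmt3l had 2 counts in the knockout DI libraries, with a wild-type to knockout ratio of 96.8 and a 95% counting interval of 26.4 to 805. The other large increases were those of Hspa1b at 4.76, St3gal6 at 4.49, Zfp971 at 3.77, Fhad1 at 3.68, Plagl1 at 3.68 and Lipg at 3.61. Prm1, a protamine of sperm chromatin, had 3 counts in the wild-type DI libraries and a knockout to wild-type ratio of 60.4 with a counting interval of 20.4 to 295. Libraries were amplified by PCR without molecular identifiers, so such intervals and floors cover counting error only. Hmox1 was lower by -1.82 ± 0.24 (edgeR adjusted p = 0.00037). Keap1, the NRF2 repressor, was lower by -0.93 ± 0.28 with edgeR adjusted p = 0.0341, which became 0.272 without wild-type DI replicate 2, and Atf3 differed by -0.26 ± 0.29.

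By group, 27 of 30 NRF2 target genes were lower in knockout DI cells (28 adjusted over the list alone), with a median of -3.46, or -3.43 with a member lacking counts at its bound (camera adjusted p = 6.46e-29; adjusted p = 0.0384 with an estimated correlation). Of 28 integrated stress response genes, 14 were higher (14 adjusted over the list alone), including Nupr1 at 2.23, Ddit3 at 1.83 and Trib3 at 1.51 (camera adjusted p = 0.000355; adjusted p = 0.107 with an estimated correlation; 9 genes without wild-type DI replicate 2). Of 14 heat shock genes, 5 were higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.00714; adjusted p = 0.172 with an estimated correlation; 3 higher without wild-type DI replicate 1 or knockout DI replicate 1). Of 28 cell cycle genes, 7 were higher and 1 lower (9 and 1 adjusted over the list alone), with Kif11 at 1.76 (camera adjusted p = 0.00663; adjusted p = 0.144 with an estimated correlation; 4 higher without wild-type DI replicate 2 or knockout DI replicate 1). Of 27 inflammatory genes, 10 were higher and 4 lower (12 and 4 adjusted over the list alone), with Ccl7 at 1.51 and Cxcl2 at 1.28 higher and Tnfaip3 at -2.38 and Ptgs2 at -1.66 lower (camera adjusted p = 0.107; adjusted p = 0.0392 with the A-rich sequence trend removed). Of 21 glycolysis genes, 7 were lower and 1 higher (8 and 2 adjusted over the list alone), with Pkm and Slc2a1 both at -2.11 (camera adjusted p = 0.00714; adjusted p = 0.178 with an estimated correlation). Of 8 MHC class II genes, 4 were lower (5 adjusted over the list alone), including H2-Aa at -1.53 (camera adjusted p = 0.01; adjusted p = 0.144 with an estimated correlation). Of 25 lysosome genes, 6 were lower and 1 higher (9 and 1 adjusted over the list alone), with the glycoprotein gene Gpnmb at -1.96 (camera adjusted p = 0.0208; adjusted p = 0.144 with an estimated correlation; 2 lower without knockout DI replicate 1 and 3 without wild-type DI replicate 1). With the A-rich sequence trend removed, 2 glycolysis and 0 lysosome genes were higher.

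Signs of other cells and of RNA quality moved with genotype in the same comparison. Of 9 stromal markers, 7 were lower in knockout DI cells (7 adjusted over the list alone), with a median of -1.58, Col3a1 at -3.10, Sparc at -1.91 and Col1a1 at -1.82 (camera adjusted p = 0.000701; adjusted p = 0.117 with an estimated correlation). In the wild-type libraries Sparc stood at 57.2 ± 1.03 CPM untreated and 85.9 ± 18.2 CPM with DI, and in the knockout at 20.2 ± 6.29 and 22.9 ± 6.58 CPM. DI itself changed 1 stromal marker in each genotype, raising Acta2 by 1.02 in wild type (lost in 7 of 8 fits without 1 library, adjusted over the list alone, with DESeq2 and with the A-rich sequence trend removed, and at adjusted p = 0.283 without wild-type untreated replicate 2) and lowering Col3a1 by 2.39 in the knockout (adjusted p = 0.0554 without knockout untreated replicate 1). Of 13 mitochondrial transcripts, 5 were lower (6 adjusted over the list alone; camera adjusted p = 0.0137; adjusted p = 0.503 with an estimated correlation; 2 without knockout DI replicate 1). Of 10 neutrophil markers, Csf3r fell with DI in wild type at -0.93 (4 lower adjusted over the list alone; camera adjusted p = 0.0417; adjusted p = 0.317 with an estimated correlation; adjusted p of Csf3r 0.136 without wild-type untreated replicate 2), and S100a8 had -0.74 in knockout DI cells (camera adjusted p = 0.95), which was lost without wild-type DI replicate 2, without any of the knockout libraries, adjusted over the list alone and with the A-rich sequence trend removed. With that trend removed 2 neutrophil markers fell with DI in wild type. Of 6 dendritic cell markers, Clec9a was higher and Itgax lower in knockout DI cells at 2.06 and -1.49 (camera adjusted p = 0.95), the former lost without any of the wild-type libraries and both without knockout DI replicate 1. Of 4 lymphocyte markers, Ebf1 was lower at -1.89 (camera adjusted p = 0.918). Neither of 2 mast cell and basophil markers was called by edgeR or DESeq2, with 1 at an unadjusted p under 0.05 and 1 passing adjusted over the list alone (camera adjusted p = 0.797), although 1 was called without either wild-type untreated library. The erythroid markers summed to 0 to 8 counts per library and were not tested. For the mitochondrial transcripts between DI-treated genotypes fry gave adjusted p = 0.0884, which did not pass.

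In DI edgeR called 1266 genes higher and 1079 lower in the knockout (2345 in all; DESeq2 called 1319 and 1012). The counts were 654 and 744 without wild-type DI replicate 1, 840 and 757 without replicate 2, and 688 and 520 without knockout DI replicate 1. With the A-rich sequence trend removed, 996 were higher and 868 lower (53.4% higher against 54.0%). Among genes with at most 9 A in any 15 coding bases, 284 were higher and 653 lower. Of 21 named calls, 20 were kept without each library in turn.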

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

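The removal of the trend with A-rich coding sequence, the comparison of library pairings and the heat shock counts without each library were tests chosen only after the result was seen. All results in this part were picked out by the test of the difference between genotypes, the interaction term, in which the DI response of knockout cells is set against that of wild-type cells. By this test edgeR called 549 genes with a higher and 287 with a lower response in the knockout.

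Among single genes, the interaction was positive for Hspa1a at 4.53, Uaca at 4.20, Hspa1b at 4.14, Anp32a at 3.38, Vti1b at 3.07, Sdccag8 at 2.95, Ddit3 at 2.85, Dhx40 at 2.72 and Nfkbiz at 1.43. It was negative for Acod1 at -1.96, Clec4n at -3.54, Gclc at -3.58, Prdx1 at -3.64, Gss at -3.65, Gclm at -3.69, Cyb5a at -3.79, Cat at -3.91 and Ptgr1 at -4.49. Among lists, the interaction term gave camera adjusted p = 6.97e-21 for NRF2 targets, 0.0082 for the integrated stress response, 0.000697 for heat shock genes, 0.0102 for cell cycle genes, 0.0493 for lysosome genes and 0.0444 for each of the glycolysis, p53, mitochondrial and ribosomal lists. All 9 list calls were lost with an estimated correlation (adjusted p = 0.0713 for NRF2 targets to 0.586 for mitochondrial genes), and the last 5 also with the replicate number as a block (adjusted p = 0.0528 to 0.0603).

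The excess of higher over lower responses in the knockout lay among genes with A-rich stretches in the coding sequence, although 60.3% of calls were higher with the trend removed against 65.7% before. In a linear regression on sequence features, the highest A count in 15 bases kept a coefficient of 0.103 (bootstrap SE over genes 0.0136) log2 per SD. The coding A fraction, GC content and length had larger coefficients of 0.369, 0.183 and 0.127. These features overlap, since GC content had a positive coefficient but a Spearman rho of -0.24 with the interaction. The regression therefore cannot decide whether coding A fraction, GC content or length alone accounts for the trend. Of 105 ways to pair the 8 libraries, only 1, the real one, gave within-pair differences of the trend this small. The trend was noticed through the group comparison itself, so this cannot decide against library-to-library variation unrelated to the groups. Within a group, the wild-type untreated libraries had slopes of -0.0049 and 0.056 log2 per A. Priming of the oligo-dT primer at A-rich coding stretches may contribute. The coefficient of A windows exceeded that of T windows by 0.0962 (bootstrap SE 0.0196), as priming predicts. This cannot decide for priming, because the trend with A was already known from these data. Other causes linked to A content could give the same excess. A real difference in the transcripts of A-rich genes between the groups remains open and was not tested, so the split of 549 against 287 is less firm than the calls that the trend's removal left in place.

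The trend with the A classes, as removed by the offset, did not account for the larger heat shock response of knockout cells. The median interaction of the list was 1.02 (bootstrap SE over its genes 0.419) after the trend's removal and 1.20 before. That SE does not measure the spread between libraries. The offset takes out only the median per class of A count, so trends with coding A fraction, GC content or length may remain. For the list's median, 1 unusual library was argued against as well, since it stayed between 0.91 and 1.24 without each of the 8 libraries. Some heat shock genes also kept an interaction call without each library. Hspa1a and Hspa1b alone are enough for that, so the calls cannot decide whether 1 library drove the rest of the list. That cells lacking NRF2 mount a stronger heat shock response to this electrophile is a hypothesis that restates the interaction, and these data hold no separate test of it. The list's median knockout minus wild-type difference was 0.44 with DI and -0.24 in untreated cells. The list's camera call was lost with an estimated correlation (adjusted p = 0.217), and reads of Hspa1a and Hspa1b may be shared between these copies.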

How the results depend on the processing

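The removal of the A trend, and the restriction to genes with at most 9 A in 15 coding bases, were tests chosen only after the result was seen. Of 197 results for named genes, 178 of them called, direction and side of the threshold were kept by 197 with median-of-ratios factors, 190 without the count filter, 187 with DESeq2, 180 with the A trend removed and, of those it applies to, 157 in fits of only the 4 libraries of a comparison. Leaving out each library in turn kept 1341 values, weakened 220, strengthened 4 and reversed 11. The reversed values belonged to genes that were not called. Without 1 library the change of Nfe2l2 with DI in wild type ranged from -0.35 to 0.63, that of Keap1 with DI in the knockout from -0.019 to 0.21, the interactions of Atf3 and Nqo1 from -0.36 to 0.51 and from -0.30 to 1.32, the difference of Acod1 between untreated genotypes from -0.20 to 0.33 and that of Atf3 in DI from -0.66 to 0.22. With the A trend removed the interaction of Atf3 was -0.39, and with DESeq2 that of Nqo1 was -0.31. The cause was not tested for Atf3, while the fitted values of Nqo1 have no meaningful size or sign, as untreated knockout libraries held none of its counts. Without 1 library the genes called with DI in wild type ranged from 290 to 745 higher and 506 to 1001 lower, with DI in the knockout from 29 to 598 and 74 to 491, for the interaction from 137 to 609 and 101 to 324, between untreated genotypes from 1 to 16 and 10 to 65, and between genotypes in DI from 654 to 1203 and 520 to 1021. The group left with a lone library was then assumed to vary like the others, and fewer libraries were tested. Without the count filter more genes were tested, and 1029 and 668 genes were called with DI in the knockout, 1106 and 491 for the interaction and 72 and 325 between untreated genotypes. In the latter comparison DESeq2 called 34 and 142 genes and a fit of its own 4 libraries 14 higher genes, and the cause was not tested. Among genes with at most 9 A, which are fewer, 397 and 249 were called with DI in wild type, 110 and 213 with DI in the knockout, 77 and 146 for the interaction, 27 lower between untreated genotypes, and 284 and 653 between genotypes in DI. This turned the share of higher calls from 42.8 to 61.5% for DI in wild type and from 52.9 to 34.1% in the knockout. For the interaction it went from 65.7 to 34.5%, and between genotypes in DI from 54.0 to 30.3%. Such shifts are expected because these genes lie at the low end of the A trend, so they do not give the shares without it. With the A trend removed over all genes these shares were, in the same order, 44.9, 50, 60.3 and 53.4%. The slope of the knockout on the wild-type response ranged from 0.081 to 0.21 and r from 0.11 to 0.24 without 1 library, and r was 0.24 with the A trend removed, and the cause was not tested.

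No strong pairing of the libraries by replicate number was seen, since deviations of libraries with the same number correlated at -0.08 to 0.16 between groups. With 2 libraries per group these correlations cannot exclude a weaker pairing. With the replicate number as a block, 703 and 971 genes were called with DI in wild type, 501 and 430 with DI in the knockout, 564 and 281 for the interaction, 9 and 58 between untreated genotypes and 1261 and 1048 in DI. Of 197 results for named genes, 4 were weaker and 193 kept under the block. Among lists, the block ended interaction calls of lysosome (0.0603), glycolysis, p53 and mitochondrial (each 0.0528) and ribosomal genes (0.0603). An estimated correlation in camera ended 35 list calls, and the trend's removal ended 5 and added 2. Small changes were often missed at this depth and number of libraries. Simulated 2-fold changes were recovered at 16% for the interaction and 45% for DI in wild type. A gene that did not pass may therefore still differ. The changed genes of the simulation all had a mean above 10 CPM, so recovery at lower levels was not tested.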

Other observations

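The test of further stromal markers was written before its result was seen, and the genes named in the next paragraph were chosen after their values were seen. Genes of the macrophage list differed in both directions between DI-treated genotypes, with 4 higher and 4 lower in the knockout. The fractalkine receptor Cx3cr1 was higher by 2.83 ± 0.46, the lipopolysaccharide co-receptor Cd14 by 1.95, the mannose receptor Mrc1 by 1.73 and Maf by 1.62. Trem2, a lipid-sensing receptor, had -1.16, and Cd300a, Cd68 and Csf1r had -0.91, -0.76 and -0.72 (camera adjusted p = 0.95). The lower genes numbered 2 without wild-type DI replicate 2, either knockout untreated library or knockout DI replicate 1, and 2 with the A-rich sequence trend removed. Of 17 chaperone genes of the endoplasmic reticulum, Herpud1 was higher at 1.67 and 5 were lower, including Manf at -1.27 and Syvn1 at -1.11 (camera adjusted p = 0.675; 2 lower without wild-type DI replicate 2 and 3 without wild-type DI replicate 1 or either knockout DI library; 2 higher without knockout DI replicate 2 or with that trend removed). Nsdhl of the cholesterol list was lower at -1.41 (camera adjusted p = 0.559), and Mylip, Smpdl3a and Apoe of the sterol efflux list at -1.81, -1.46 and -0.78 (camera adjusted p = 0.0774).

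The iron exporter Slc40a1 was raised by DI in both genotypes, by 2.22 ± 0.30 in wild type and 1.58 ± 0.32 in knockout cells (edgeR adjusted p = 0.000496 and 0.0136), from a lower level in the knockout. Its interaction was -0.64 ± 0.43 and did not pass the test (edgeR adjusted p = 0.363).

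Stromal genes were lower in the knockout libraries, with a median of -1.26 over both treatments for the 9 tested markers. One library with unusual stromal content was argued against, because the median was -1.20 without the library that moved it most towards 0. More fibroblast-like cells in the wild-type cultures may account for the pattern, since all 16 tested of 18 further markers were lower in the knockout, with a median of -1.61 (bootstrap SE 0.178). That SE comes from resampling the markers and does not measure the spread between libraries. The lowest edgeR adjusted p among these markers, that of Bgn, was 0.0565 in untreated cells and 0.000113 in DI. Macrophages also express some of these genes at low levels, and an effect of genotype on stromal genes within macrophages was not tested. The most abundant further marker in untreated wild-type cells, Fstl1, stood at 16.5 and 8.54 CPM there.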
